A study of Mus musculus with 6 samples.

How the data were processed

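Gene expression was measured in the visual cortex of adult wild-type (C57Bl6) mice after monocular enucleation, the removal of one eye. In mice most fibres of each optic nerve cross the midline, so the hemisphere contralateral to the removed eye is the deprived one and the ipsilateral hemisphere is the non-deprived one. Per the labels' protocols, 4 mice were enucleated at postnatal day 100 and killed 4 days later, visual cortex was dissected from coronal sections, RNA was extracted with Trizol, and about 10 µg of total RNA was made into biotinylated cRNA. The series compares 3 arrays of deprived with 3 arrays of non-deprived cortex, and its design text speaks of pooled samples. How many mice a pool held, and whether the 3 arrays of a group came from separate pools, is not stated, so p-values measure only the spread between these samples, which may be technical.

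The authors deposited 1 table of 12488 probe sets by 6 arrays, whose values are MAS5 signal intensity on a linear scale. MAS5 is named in the submitters' processing notes. It summarises each probe set from perfect-match and mismatch probes and gives an arbitrary brightness unit, not a count of molecules. The deposited intensity columns all had a 2% trimmed mean of 500.3, so the arrays stood at a common level as deposited. Such scaling hides any change in the total amount of mRNA. Scanner files and detection calls were not used here, so a dim probe set could not be told from background.

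Array values were brought to the common 2% trimmed mean, which left them as they were, and the 66 control probe sets were set aside. Probe sets in the top 60% of mean signal over all 6 arrays (7453 probe sets, mean signal of at least 134.7) were tested on log2(signal + 16). The pseudocount of 16 makes fold changes of low signals smaller than they are on the linear scale. Deprived and non-deprived arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with group as the only term and Benjamini-Hochberg adjustment over all probe sets tested; adjusted p under 0.05 was the threshold. Adjusted p-values of single genes below come from this fit. Every log2 change is deprived minus non-deprived.

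Gene names came from the platform annotation supplied with the series, updated through the Entrez gene ID to NCBI RefSeq's mouse table (assembly GRCm38.p6, used for names only). Of the probe sets, 10855 had 1 gene symbol, 396 had several and were left unnamed, and 1237 were unnamed here. Of those with 1 symbol, 10839 matched by ID and no symbol changed. For gene lists, each of 5653 genes was represented by its probe set with the highest mean signal. Probe sets whose names carry _f, _r or _i were designed with fewer constraints or can share probes with related transcripts, and are marked where they matter.

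Before the data were examined, 28 gene lists were fixed, covering activity-dependent genes, signalling, synapses, metabolism, stress, cell types and neighbouring brain regions. The 26 lists with at least 5 measured members were tested with camera (limma), which asks whether a list's members shift relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists. camera with an estimated correlation and fry were the alternatives; fry's directional test asks whether a list's genes move, on balance, one way. Members were also counted by p-values adjusted over the list alone. The mean log2 signal of each list per array was compared between groups with a two-sided exact permutation test, for which 0.1 is the smallest p that 3 against 3 arrays can give.

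The genes named were chosen by a rule fixed beforehand: up to 12 probe sets with the largest rise and 12 with the largest fall among those past the threshold (the 10 genes with the smallest p if fewer than 10 passed in all); a set of 17 activity and marker genes; the 2 members of each list with the smallest p; and up to 6 members per list, by size of change, past the threshold over the list alone. Arc and Egr4, on that set, had no tested probe set with their name and are not analysed here. Where a gene has several probe sets, the brightest is given, except that each probe set past the threshold is given too, and those with the opposite sign or a log2 change differing by over 0.5 are named. Alternatives fixed beforehand were quantile normalization, the values without further scaling, pseudocounts of 1 and 64, no filter, the top 40% of mean signal, the replicate number as a block, leaving out each array in turn, eBayes without the intensity trend, a threshold of 0.10, 1 probe set per gene, and the mean of a gene's probe sets. Counts without _f, _r and _i probe sets, and list counts without each array, were added after seeing the data.

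The fit was tested on simulated data: 20 simulated sets of 7453 probe sets, with the tested probe sets' means and within-group spread and 200 probe sets changed in each. It recovered 23.9% of 1.5-fold, 57.9% of 2-fold and 89.5% of 4-fold changes, and 4.85% of all calls were false. The real data gave 13 calls, so fewer than 200 probe sets may have changed, and recovery would then be lower. In 100 simulations of 5653 genes, a list of 15 genes lowered by 0.5 (log2) was called in 100% of runs and an unchanged list in 1%, at an unadjusted camera p under 0.05. These simulated genes varied independently, so the 1% does not cover lists whose genes vary together. The shift of 0.5 is also larger than the medians of the effector gene and feedback regulator lists below (-0.20 and -0.15). The number of arrays limits precision: the median standard error of a log2 change was 0.181.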

Results

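The data comprise 6 arrays of visual cortex from adult mice, 4 days after removal of one eye: 3 of the deprived hemisphere and 3 of the non-deprived hemisphere. Median signal ranged from 202.8 to 219.7 across arrays. Log2 signals of any pair of arrays correlated across probe sets at 0.948 to 0.958 within a group and 0.945 to 0.961 between groups, and no pair held identical values. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 1.38 ± 0.118 (SD, n = 3) for β-actin in non-deprived and 1.46 ± 0.186 in deprived arrays (exact permutation test, two-sided, p = 0.7), and 1.01 ± 0.0792 against 1.02 ± 0.0499 for Gapdh (exact permutation p = 0.9). One array stood apart in a control: the 3′ probe set for 18S ribosomal RNA read 2689 in non-deprived replicate 3 and 661 to 981 in the other 5 arrays. Of the 66 control probe sets, 0 differed between groups by limma with adjustment over the controls (smallest adjusted p = 0.608) and 1 had an unadjusted p under 0.05.

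The comparison asks which transcripts differ between cortex that lost its main eye input and cortex that kept it, at an adult age. The genes that fell in deprived cortex were mainly those that neurons switch on within minutes of activity. Fos, an immediate-early transcription factor subunit, fell 4.13-fold, from 2946 ± 236 to 703 ± 87.7 signal units (mean ± SD, n = 3 arrays per group; log2 change -2.05, SE 0.12, limma adjusted p = 0.00014). Egr2, a zinc-finger transcription factor, fell 2.97-fold from 1335 ± 147 to 439.5 ± 50.6 (adjusted p = 0.0011). Junb, a partner of Fos, fell 2.69-fold and 2.20-fold on its _r and _i probe sets (adjusted p = 0.0014 and 0.0011). The nuclear receptor Nr4a1 fell 2.47-fold from 2188 ± 104.4 to 876 ± 26.7, and Egr1 fell 2.19-fold from 6248 ± 326 to 2846 ± 211 (adjusted p = 0.00048 for both). Dimmer, untested probe sets of Fos and Egr1, with mean signals of 129.5 and 125.7, had log2 changes of -0.64 (SE 0.36) and -0.49 (SE 0.56).

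Dusp1 and Dusp6, phosphatases that switch off MAP kinases, fell 2.19-fold and 2.12-fold (2903 ± 210 to 1318 ± 113, and 1841 ± 253 to 853 ± 17.9; adjusted p = 0.0014 and 0.0059). Ier2, another immediate-early gene, fell 2.10-fold (adjusted p = 0.031). Bdnf, a neurotrophin, fell 1.92-fold from 1366 ± 123 to 707 ± 123 (adjusted p = 0.045). In all, 13 of 7453 probe sets passed, 12 lower and 1 higher. For each of the 13 the arrays of both groups did not overlap, which passing this test makes nearly certain, so it adds no further support. The 13 probe sets represent 12 named genes, of which 9 stood on the 3 lists of activity-dependent and MAP kinase feedback genes fixed beforehand.

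The other 3 were outside those lists. Slc25a17, which encodes a peroxisomal membrane carrier, rose 1.78-fold from 946 ± 66.2 to 1702 ± 206 (log2 change 0.83, SE 0.12, adjusted p = 0.040). A _f probe set assigned to Snrp1c-ps2, named as a pseudogene, fell 2.51-fold (adjusted p = 0.043), and its signal is uncertain because it can come from related transcripts. For Cx3cl1, a chemokine that neurons make, the brightest probe set read 13880 ± 391 in non-deprived and 10860 ± 962 in deprived arrays (log2 change -0.36, SE 0.08, adjusted p = 0.28). A dim _r probe set of Cx3cl1 fell from 304 ± 58.7 to 47.1 ± 8.40 (log2 change -2.33, SE 0.34, adjusted p = 0.039). Its deprived mean lies under the 134.7 that the filter asked of the mean over all arrays and is not shown to be above background, so the size of the fall is uncertain; the log2 change ranged from -2.66 to -1.72 over 13 alternatives.

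Fos, Egr1, Egr2, Junb, Nr4a1 and Dusp1 passed under all 14 alternatives run for named genes. Dusp6 passed in 12 of the 14, with adjusted p from 0.0027 to 0.0745, and lost its call without non-deprived replicate 2 and without the intensity trend. Ier2 and the dim Cx3cl1 probe set lost their calls whichever array was left out, and Bdnf and Slc25a17 kept theirs only without deprived replicate 2, and Snrp1c-ps2 only without non-deprived replicate 1, while each changed in the same direction in every one of these fits (log2 -1.16 to -1.01 for Ier2, -2.49 to -2.23 for the Cx3cl1 probe set, -1.08 to -0.86 for Bdnf, 0.75 to 0.93 for Slc25a17, -1.52 to -1.14 for Snrp1c-ps2). The number of calls was 7 without non-deprived replicate 2, 8 without non-deprived replicate 3 and 8 without deprived replicate 3. In all, 379 probe sets had an unadjusted p under 0.05 (180 lower, 199 higher), against 373 that chance gives. The groups' arrays did not overlap for 752 probe sets, which is 10.1% of those tested, where chance gives 10%.

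**Figure D1:**
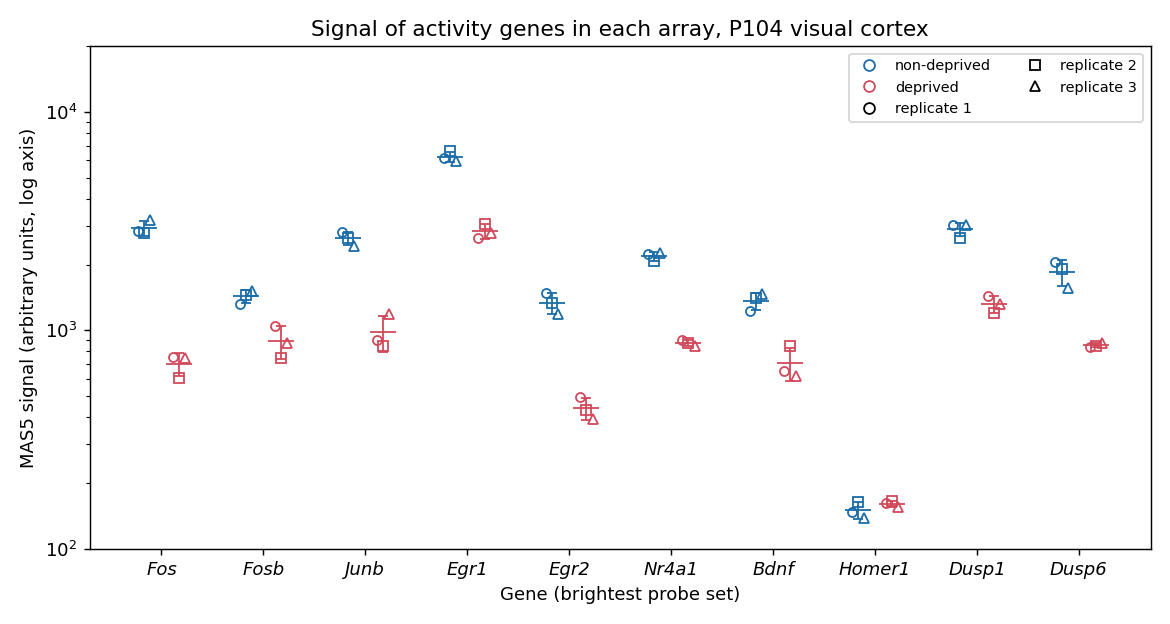
MAS5 signal (log axis, arbitrary units) of 10 activity genes in each array; symbols are replicates, horizontal bars with whiskers are mean ± SD of the 3 arrays of a group. For 9 of the 10 genes every deprived array lies below every non-deprived array. Homer1 is the exception, at signals of 138.5 to 164.9 that are not shown to be above background.

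Activity-induced transcription factors fell as a group. Of 16 measured members, 15 had a lower mean in deprived arrays, with a median log2 change of -0.75. Fos, Egr2, Junb, Nr4a1, Egr1 and Ier2 (6 members) fell by the adjustment over all probe sets, and 9 fell when adjusted over the list alone. The additional 3 were Fosb (1434 ± 99.6 to 891 ± 155, 1.61-fold), Btg2 (1.86-fold) and Klf10 (1.41-fold); Btg2 and Klf10 are named after their values were seen. None of the 16 rose by either adjustment. The remaining 7 did not pass, among them Jun (log2 change -0.15, SE 0.19), Atf3 (-0.06, SE 0.23) and Nr4a2 (-0.40, SE 0.24), which are named after their values were seen. The list shift had an adjusted p of 4.97e-24 by camera, with an adjusted p = 0.0093 with an estimated correlation. Without non-deprived replicate 3, the array with the high 18S signal, the number of members that fell when adjusted over the list alone was 9.

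Activity-induced effector genes, whose products act at synapses, in secretion or on the cell cycle, had a median log2 change of -0.20 over 14 members. The list passed camera with the preset correlation (adjusted p = 0.00011) and lost that call with the estimated one (adjusted p = 0.0993 with an estimated correlation). By the adjustment over all probe sets 1 fell (Bdnf), and 3 fell when adjusted over the list alone: Bdnf, the granule protein Scg2 (944 ± 62.6 to 683 ± 52.3, 1.38-fold) and the stress-response gene Gadd45b (388 ± 39.7 to 254 ± 9.22, 1.49-fold). The other 11 did not pass over the list alone. The count over the list alone dropped to 1 without non-deprived replicate 1, without non-deprived replicate 2, without deprived replicate 2 or without deprived replicate 3. Without deprived replicate 1, Gadd45b did not pass, Bdnf, Scg2 and Cdkn1a fell and the neuropeptide gene Cort rose; Cdkn1a and Cort are named after their values were seen. Homer1, which encodes a postsynaptic scaffold protein, read 150 ± 12.9 in non-deprived and 161 ± 5.52 in deprived arrays (log2 change 0.09, 95% interval -0.51 to 0.70), and its dimmer, untested probe set had a log2 change of -0.85 (SE 0.50). The tested Homer1 signal lies close to the filter's 134.7 and is not shown to be above background, so an unchanged level is not established.

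MAP kinase feedback regulators had a median log2 change of -0.15 over 9 members, of which 2 fell by either adjustment (Dusp1 and Dusp6). The median was -0.39 without non-deprived replicate 1, -0.29 without deprived replicate 2 and -0.25 with only the top 40% of probe sets by signal. Its camera test passed with the preset correlation (adjusted p = 0.00018) and lost that call with the estimated one (adjusted p = 0.0993 with an estimated correlation). The ERK cascade itself, the signalling proteins that these phosphatases act against, had a median of 0.04 over 9 members, none past the threshold over the list alone; Rasgrp1 had a log2 change of -0.65 (SE 0.30) and Nras 0.26 (SE 0.16), with -0.02 (SE 0.20) on its other probe set. The exact permutation test of the per-array list means gave p = 0.1, the smallest it can give, for each of the 3 lists that passed and also for 2 that did not pass camera, endothelium and blood vessel wall (camera adjusted p = 0.639) and cytosolic ribosomal proteins (0.699). By fry, the same 3 lists passed in the directional test (adjusted p = 0.00011 for the transcription factors, 0.0092 for the effector genes and 0.0085 for the feedback regulators).

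None of the other 23 tested lists passed camera (smallest adjusted p = 0.132); their medians lay between -0.16 and 0.15. Among GABAergic neuron genes (14 members, 8 lower and 6 higher, median -0.11), 2 neuropeptides fell when adjusted over the list alone. Sst (somatostatin) went from 4521 ± 304 to 3446 ± 50.9, a 1.31-fold fall, and Npy (neuropeptide Y) from 2509 ± 184 to 1882 ± 212, a 1.33-fold fall (adjusted over the list alone; 0.26 and 0.59 over all probe sets). Without non-deprived replicate 1 neither passed, without deprived replicate 2 or non-deprived replicate 3 the list's count was 1, and without deprived replicate 1 it was 4 lower and 1 higher. Pvalb, the calcium-binding protein of fast-spiking interneurons, read 4917 ± 269 and 4149 ± 583 on an _i probe set (log2 change -0.25, SE 0.11) and did not pass. The list's other measured neuropeptides, named after their values were seen, went both ways without passing. Cort had a log2 change of 0.81 (SE 0.33), Vip 0.19 (SE 0.20) and Cck -0.20 (SE 0.09). camera gave the list an adjusted p of 0.132, or 0.0033 when only the top 40% of probe sets by signal were tested. The list's median was -0.16 with that top 40% and -0.01 with no filter on dim probe sets.

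Lists of synapse and excitability genes did not pass camera. Glutamate receptors and postsynaptic density genes had a median of 0.00 over 14 members (Dlg4 0.18, SE 0.10; Baiap2 -0.21, SE 0.11). Vesicle and release genes had a median of 0.02 over 15 members (Rab3a 0.73, SE 0.30; Nsf -0.29, SE 0.17), and GABA-A receptor subunits -0.06 over 6 (Gabra2 -0.41, SE 0.15; Gabrd -0.26, SE 0.21). Voltage-gated ion channels had a median of 0.01 over 17; the potassium channel gene Kcnd3 fell from 361 ± 71.2 to 137 ± 75.9 when adjusted over the list alone (adjusted p = 0.43 over all probe sets). Its deprived signal is not shown to be above background, so the size is uncertain, and of the fits without 1 array it passed only in that without deprived replicate 3. Kcnj4 had a log2 change of 0.36 (SE 0.13).

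Lists of markers of other cell types did not pass camera. Astrocyte genes had a median log2 change of 0.06 over 17 members. Gfap, the astrocyte intermediate filament, read 986 ± 23.2 and 987 ± 93.8 (95% interval of the log2 change -0.26 to 0.26), while its dimmer probe set had a log2 change of 1.04 (SE 0.59). Aldoc had -0.25 (SE 0.10) and Vim 0.59 (SE 0.32). Microglia genes had a median of 0.06 over 10 (Ctss 0.16, SE 0.10; Cx3cr1 -0.29, SE 0.20). Oligodendrocyte and myelin genes had 0.04 over 11 (Sox10 0.24, SE 0.11; Cldn11 0.21, SE 0.16), with Mbp at 5403 ± 504 and 5644 ± 465 and a 95% interval of -0.15 to 0.28; its dimmer probe set had a log2 change of -0.19 (SE 0.14). Endothelial and vessel-wall genes had -0.16 over 9 (Cldn5 0.40, SE 0.19; Tagln -0.42, SE 0.29). Meninges and choroid plexus genes had -0.04 over 7 (Ptgds 0.14, SE 0.12; Slc6a13 0.20, SE 0.15). Red blood cell genes (4 members, untested) had -0.07 (Hbb-b2 -0.08, SE 0.15; Slc4a1 -0.29, SE 0.49).

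Neighbouring regions and cortical layers gave medians of -0.12 for thalamus (7 members; Lef1 -0.43, SE 0.21; Tcf7l2 -0.18, SE 0.16, with 0.08, SE 0.29, on a dim one), 0.15 for hippocampus (8 members; Wfs1 0.41, SE 0.17; Neurod6 0.49, SE 0.29) and -0.07 for striatum (4 members, untested; Penk -0.11, SE 0.16, with 0.79, SE 0.42, on another probe set; Pdyn 0.10, SE 0.18). Upper-layer genes had 0.05 over 8 (Cux2 -0.41, SE 0.34; Pou3f2 0.42, SE 0.34). Deep-layer genes had -0.09 over 9; Fezf2, a transcription factor of deep-layer projection neurons, had a log2 change of -0.45 (SE 0.13) and Ccn2 -0.54 (SE 0.21), and neither passed over the list alone.

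MHC class I and complement genes had a median of 0.07 over 10 members; B2m, the light chain of MHC class I, read 980 ± 184 and 1054 ± 170 (95% interval -0.26 to 0.47), H2-K1 had -0.19 (SE 0.15; 0.52, SE 0.37, on another probe set) and Tap1 0.42 (SE 0.24; -0.19, SE 0.62, on a dim one). Insulin-like growth factor and matrix genes had 0.01 over 12 (Igfbp4 0.58, SE 0.18, with -0.16, SE 0.21, and -0.79, SE 0.46, on its other probe sets; Igf1r 0.24, SE 0.15). Circadian clock genes had -0.03 over 16 (Npas2 0.92, SE 0.32; Tef 0.29, SE 0.11), heat shock and chaperone genes -0.07 over 16 (Hspa4 -0.19, SE 0.11, with 0.18 to 0.27 on 3 other probe sets; Hspd1 0.27, SE 0.16) and cytosolic ribosomal proteins -0.02 over 27. Rps13 fell 2.17-fold when adjusted over the ribosomal list alone, on an _r probe set of a family with many near-identical copies, and is uncertain; of the fits without 1 array it passed only in that without non-deprived replicate 3. Rps19 had a log2 change of 0.31 (SE 0.11).

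Among glucocorticoid-responsive genes (14 members, median -0.05), 3 passed over the list alone: Dusp1, which also stands on the feedback list, Klf9, which fell 1.29-fold (4025 ± 58.1 to 3128 ± 213), and Ddit4, which rose 1.61-fold (384 ± 69.9 to 624 ± 70.4). Over all probe sets the adjusted p was 0.35 for Klf9 and 0.50 for Ddit4. Without deprived replicate 2 or without deprived replicate 3, 0 members of the list rose when adjusted over the list alone, so Ddit4 did not pass there. A dimmer probe set of Klf9, at a mean signal of 670, had a log2 change of -0.01 (SE 0.17) and did not show the fall. Oxidative phosphorylation genes had a median of -0.06 over 64 (Atp5mpl -0.51, SE 0.17; Ndufb11 -0.27, SE 0.11) and glycolysis genes -0.06 over 15 (Aldoc, above, and Ldha -0.22, SE 0.10), each with a camera adjusted p of 0.132. Without non-deprived replicate 3, the array with the high 18S signal, the glucocorticoid (adjusted p = 0.0032), oxidative phosphorylation and glycolysis lists (adjusted p = 0.0046 for both) passed as lower; oxidative phosphorylation also passed without deprived replicate 3 (adjusted p = 0.033). The median, the mean and the camera direction differed in sign for the glutamate receptor, vesicle release, ion channel, meninges and circadian clock lists.

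**Figure D2:**
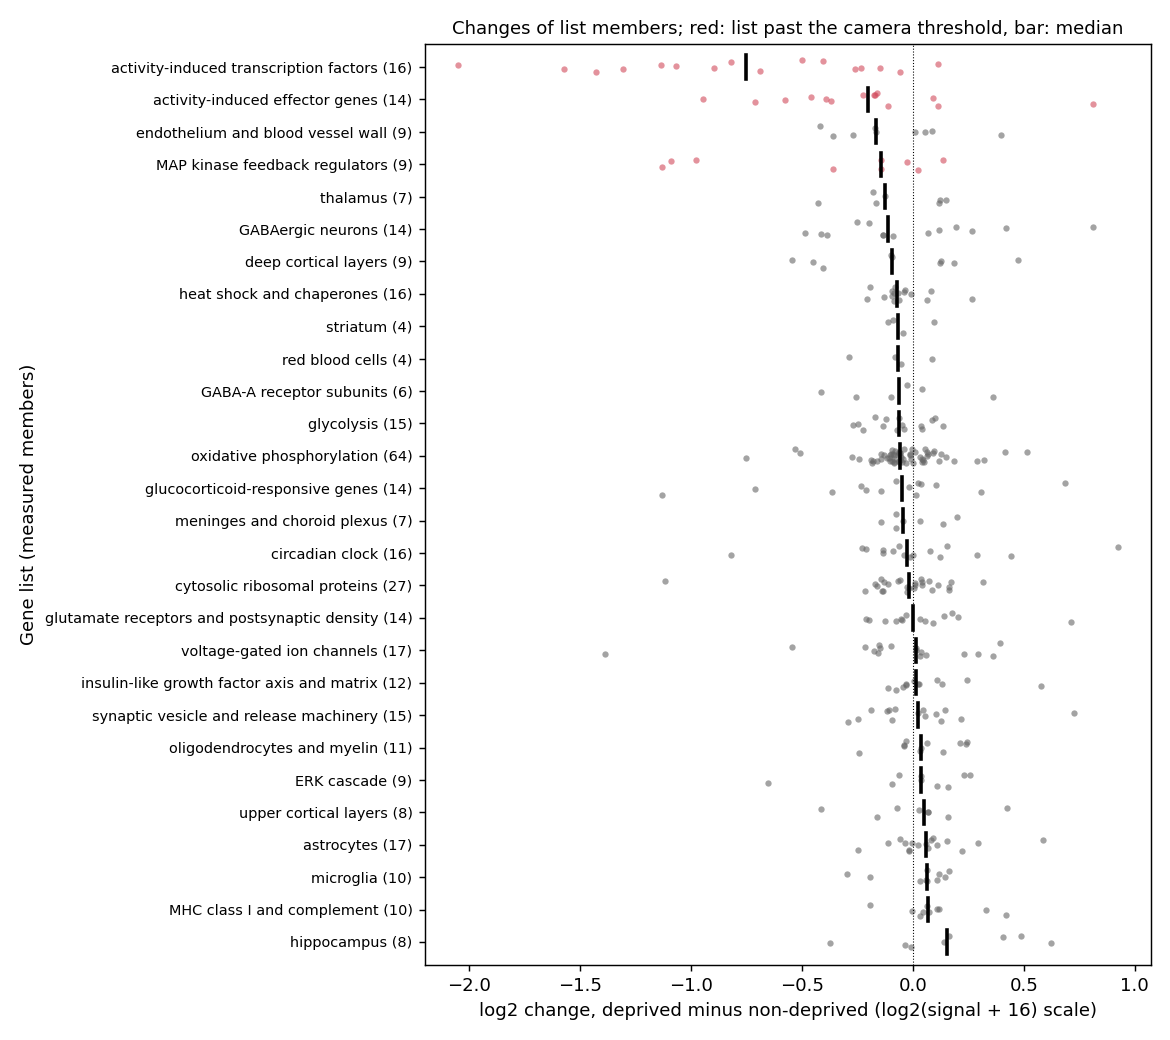
Log2 change (deprived minus non-deprived, log2(signal + 16) scale) of each measured member of the 28 lists; points are genes, black bars list medians, and red marks the 3 lists past the camera threshold. The activity-induced transcription factors lie farthest to the left with a median of -0.75, and the medians of the 23 tested lists that did not pass lie between -0.16 and 0.15.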

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

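The counts without _f, _r and _i probe sets, and the counts over a list alone without each array, were chosen only after the result was seen. Of the 13 probe sets past the threshold, quantile normalization kept 12, both other pseudocounts kept 13, the top 40% filter kept 12, testing with no filter on dim probe sets kept 9 of 13 (of 9 calls) and eBayes without the intensity trend kept 8 (of 10 calls). With 1 probe set per gene 11 passed, at an adjusted p under 0.10 14 passed, and without _f, _r and _i probe sets 9. Besides the fits that left out an array, Ier2 and Bdnf lost their calls with no filter (adjusted p = 0.0534 and 0.0774), with the replicate block (0.061 for both) and without the intensity trend (0.0745 and 0.253), Bdnf also with quantile normalization (0.0532), Slc25a17 and Snrp1c-ps2 with no filter (0.0534 and 0.0857) and without the intensity trend (0.244 and 0.196), and the dim Cx3cl1 probe set with the replicate block (0.156). Using the values without further scaling moved nothing, since the arrays were already scaled. With the replicate block, 10 passed and all 3 activity lists kept their calls; deviations of same-numbered arrays from their group means correlated at 0.003, 0.049 and -0.02, so the numbers were not read as pairs, and only 1 of the 3 non-deprived arrays correlated best with its own number. Leaving out each array in turn gave 7 to 10 calls (fewer arrays leave fewer degrees of freedom) and 3 to 6 lists past the threshold, 6 without non-deprived replicate 3. An estimated inter-gene correlation left 1 list, the transcription factors, and gave an adjusted p of 0.0993 to both the effector genes and the feedback regulators. Genes whose small, uncalled change turned sign when an array was left out, with the range of log2 change: Gfap -0.0768 to 0.0519, Pou3f2 -0.014 to 0.65, B2m -0.0096 to 0.25, Hbb-b2 -0.20 to 0.0181, Slc4a1 -0.68 to 0.22, Penk -0.20 to 0.0214, Mbp -0.0128 to 0.12, Ptgds -0.0226 to 0.25. No detection calls were used, so how far dim signals stand above background is unknown.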

Other observations

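The tests of array scaling, short-lived mRNA, probe design class, peptide secretion genes and other splits of the arrays had their outcomes written before the result was seen; those of the share of neurons and of the pair of Cx3cl1 probe sets were chosen only after the result was seen.

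Beyond the fixed lists, several other genes had lower means in deprived arrays without passing the adjustment over all probe sets, and they are named after their values were seen. Nab2, a co-repressor that binds Egr proteins, had a log2 change of -0.44 (SE 0.13), Midn -0.63 (SE 0.14), Sertad1 -0.95 (SE 0.32) and Dnajb5 -1.91 (SE 0.53). Chgb, a granule protein abundant in neurons, went from 10590 ± 343 to 8544 ± 738 (log2 change -0.31, SE 0.08) on a _f probe set. In the other direction, Chst3, which sulfates chondroitin chains of the matrix, read 112 ± 23.7 in non-deprived and 340 ± 79.9 in deprived arrays (log2 change 1.47, SE 0.28, adjusted p = 0.16). Its non-deprived mean lies under the filter's 134.7 and is not shown to be above background, so the size of the rise is uncertain. Specc1 had a log2 change of 0.83 (SE 0.14) and Strada 1.57 (SE 0.32), the latter from a dim signal of 71.7 ± 11.8.

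The lower signal of the activity-induced transcription factors was weighed against technical explanations. After quantile normalization the list's median log2 change was -0.763 (SE 0.235 over 16 members), which lies below -0.2, the level array scaling would need, by more than 2 standard errors, though not below -0.5 by that margin, the stricter bound set before the result was seen. The arrays were already scaled alike, and the median log2 change over all tested probe sets was 0.01. Quantile normalization therefore had little to move (the list's median was -0.753 before it), and this test could hardly have come out otherwise. A lower share of neurons would lower neuronal genes in general, but the vesicle release and glutamate receptor lists had a joint median of 0.023 (SE 0.049 over 29 members). Other short-lived mRNAs, such as Mcl1, Id2 and Klf6, had a median of -0.083 (SE 0.058 over 17 members). This argues against a general loss of labile transcripts in the deprived samples, though the spread between arrays was not computed for this list. A candidate explanation that stays open is the loss of eye input itself, which the design names and which is a hypothesis here. The order of dissection of the hemispheres, which these labels do not give, was not tested. Nor could a rise in the non-deprived hemisphere be told from a fall in the deprived one, since no unoperated mice were among the samples.

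The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of these splits, the real one, 13 probe sets passed, and the highest of the others gave 1. For the lists the real split gave 3 and the highest of the others 2, again with 1 split, the real one, reaching 3. The other splits that called any list called 2, 1 and 1. Every split but the real one has arrays of both groups on each side, so a group difference widens the spread within a side. Their counts are therefore not those of data without a difference.

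The dim Cx3cl1 probe set differed from the bright one by -1.975 in log2 change (SE 0.349). This difference is the observation itself, on a probe set singled out for its fall, so a single change of all Cx3cl1 mRNA read alike by both stays open. The bright probe set, at a mean signal of 12370, is far below the brightest signals on these arrays (69936 or more). Probe sets with _f, _r or _i in their names made up 30.8% of the 13 calls and 14.6% of those tested (one-sided Fisher's exact test, p = 0.108), so a probe design effect and a change in one transcript form cannot be told apart with so few calls.

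Sst, Npy, Scg2 and Chgb, singled out for their falls, all had lower means in deprived arrays. This raised the hypothesis that genes of peptide secretion fell as a group by at least 0.2 (log2). Of 16 further such genes listed before their values were looked at, 10 were measured; 8 were lower, with a median log2 change of -0.097 (SE 0.042) and an unadjusted camera p of 0.0441 in the lower direction. The median lies above -0.2 by more than 2 standard errors over genes, which leave out the spread between arrays. A fall of that size was not found for the group, and a smaller one may remain. Neuropeptide genes of the fixed lists that were not among the 16 went both ways. Cort (log2 change 0.81, SE 0.33), Vip (0.19, SE 0.20) and Pdyn (0.10, SE 0.18) were higher. Cck (-0.20, SE 0.09) and Penk (-0.11, SE 0.16) were lower. By fry's test for change in either direction, 5 lists passed: the 3 activity lists, GABAergic neurons (adjusted p = 0.0032) and glucocorticoid-responsive genes (adjusted p = 0.00013), the latter holding Dusp1.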
